A study of Dictyostelium discoideum with 30 samples.

How the data were processed

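The series holds RNA sequencing of the social amoeba Dictyostelium discoideum, taken from the axenic laboratory strain AX2 (the wild type) and from a mutant of the homeobox gene hbx5 after 0, 1, 2, 5 and 8 h of development. Each of the 10 combinations of strain and time has 3 libraries, 30 in all. Per the labels' protocols, RNA was prepared with Tri-reagent and libraries with a SMARTer kit. The series' design text calls the 3 libraries of a group technical replicates. P-values therefore measure only the spread between these libraries, which need not cover the spread between separate cultures.

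The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled by library size) for 13731 genes and all 30 libraries, per the file headers. The aligner, the genome build and the read counter are not given in the sources used here. The table's gene coordinates were compared with the RefSeq table of assembly dicty_2.7: 13729 identifiers matched, and for all 13729 the symbol and the start were equal, so coordinates are given on that assembly. Of the listed gene lengths, 96.4% were multiples of 3, so they are coding lengths. The FPKM values were whole multiples of what 1 read is worth for a gene of that length: with a tolerance of 0.01 reads, 100.0% of the values above 0 were whole in every library. The reads worked out in this way came to 12977573 to 23565147 per library. The library size implied by the FPKM was 0.651 to 1.318 times that total, so the authors' scaling was not a plain division by the sum. Intervals or floors from these reads would cover counting error only, since no molecular identifiers are described. No 2 libraries of a group were copies of each other, since the chi-square statistic per degree of freedom of their reads ran from 38.5 to 569.3.

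FPKM values are not counts, so the test written before the data were examined was limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), with 1 mean per strain and time over all 30 libraries and no further scaling. Genes with an FPKM of at least 1 in 3 or more libraries were tested (11356 genes, with 2375 below that level). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Differences are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The comparisons were mutant against wild type at each of the 5 times, each later time against 0 h within a strain, and the difference between the strains in that change (interaction). Adjusted p of single genes come from this limma fit, except where the text names an alternative or a library left out.

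Gene lists fixed before the data were examined were tested with limma's camera at its preset correlation of 0.01, with adjustment over 13 lists and 5 times (65 pairs), and again with a correlation estimated per list. Counts of called list members are given over all tested genes and adjusted over the list alone. Some genes belong to more than 1 list, such as csaA and carB in both the relay and the aggregation lists. Results of these lists are therefore not independent. A list of mitochondrially encoded genes had 0 members in the table. Each library was also placed on an axis from the wild type 0 h mean (0) to the wild type 8 h mean (1), over the 6199 genes called in the wild type between these times with at least a 2-fold change. Strains were compared on it with an exact two-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1. The table held 0 columns of samples outside the series.

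Genes are named by a rule fixed at the same time: hbx5; the 6 genes most raised and the 6 most lowered per strain comparison and in the wild type from 0 to 8 h, among called genes with a symbol, a mean of at least 5 FPKM in 1 group and groups that do not overlap (10% by chance for 3 against 3); all cAMP relay members; and up to 4 members of each other list per comparison, those with the smallest adjusted p. Not all genes that the rule picks are reported here; relay members not named are in the counts. Genes that the reference holds in 2 near-identical copies (symbols ending in -1 and -2) are called copy-uncertain, since reads could be divided between the copies.

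The limma, camera and axis steps were tested on simulated data of 11356 genes. In the simulated comparison of strains at 5 h, 44% of genes with a 2-fold and 93% of genes with a 4-fold change were called in the right direction, and 3 unchanged genes were called. There 200 genes were changed, each from a base level of at least 3 on the log2 scale, whereas 7427 were called in the real comparison. These rates are therefore not the power of the real comparison and do not cover genes with low values. With no gene changed at 0 h, 0 genes were called by limma. The alternatives were a pseudocount of 0.1, no filter, median-ratio scaling of the libraries, the replicate number as a block, only the groups compared in the fit, each library left out in turn, genes with a second copy left out, and an axis from genes with a 4-fold change or without the ribosomal protein and relay lists. Further alternatives chosen after seeing the data were limma voom on the reads worked out from the FPKM, leaving out 4 libraries with few genes at exactly 1 read, and leaving out the genes of a duplicated stretch of chromosome 2. Preparation and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

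Same-numbered libraries were checked for shared deviations in the 13 comparisons of 2 groups. In 2 of them every pair of same-numbered libraries had a correlation of deviations over 0.1: wild type 5 h with 0 h (0.491, 0.237 and 0.509) and mutant 2 h with 0 h (0.242, 0.397 and 0.153). That pairing comes from the data, since the labels give only numbers.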

Results

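The series asks how cells time their entry into development through rhythmic cell-to-cell signals. Starving Dictyostelium cells secrete pulses of cyclic AMP (cAMP), relay them, and gather into mounds in which prespore and prestalk cells arise. RNA was measured in wild type AX2 cells and in a mutant of the homeobox transcription factor gene hbx5, at 0, 1, 2, 5 and 8 h of development, with 3 libraries in each of the 10 groups. Depth was 12977573 to 23565147 reads per library. Within groups the log2 levels of libraries correlated across genes at 0.891 to 0.993. Values are FPKM as mean ± SD of 3 libraries, and differences are log2 ± SE with limma's adjusted p. The first principal component held 51.2% of the variance over the 30 libraries and the next one 14.4%.

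The mutated gene was read in each library first. The reference holds hbx5 in 2 copies, hbx5-1 (DDB_G0273127, chromosome 2, 2807924 to 2813408, plus strand) and hbx5-2 (DDB_G0273645, chromosome 2, 3218378 to 3223862, minus strand), within a stretch of chromosome 2 from 2268088 to 3763698 that contains an inverted duplication, so both are copy-uncertain. Libraries labelled hbx5 mutant, called the mutant from here on, still held hbx5 reads. Across all libraries 108 to 710 reads fell on hbx5-1 and 112 to 781 on hbx5-2. At 5 h hbx5-1 was at 1.48 ± 0.300 FPKM in the mutant against 5.95 ± 3.59 FPKM in the wild type (log2 difference -1.38 ± 0.35 SE, adjusted p = 0.0013), and hbx5-2 was at 2.04 ± 0.629 against 6.72 ± 3.78 FPKM (log2 difference -1.26 ± 0.40 SE, adjusted p = 0.0081). Without wild type 5 h replicate 2, the differences were -0.98 for hbx5-1 (adjusted p = 0.020) and -0.89 for hbx5-2 (adjusted p = 0.075). At the other times neither copy passed the test. At 0 h hbx5-1 was at 1.67 ± 0.0839 against 1.96 ± 0.286 FPKM (adjusted p = 0.88), mutant first. It was at 2.35 ± 1.07 against 4.41 ± 1.58 FPKM at 1 h (adjusted p = 0.14), 2.10 ± 0.492 against 2.85 ± 1.70 FPKM at 2 h (adjusted p = 0.67). At 8 h it was at 4.70 ± 1.83 against 4.08 ± 1.71 FPKM (adjusted p = 0.70). How the gene was altered is not stated in the sources used here, so the level of hbx5 does not check the labels.

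To describe normal development, each later time was compared with 0 h in the wild type. Genes of the cAMP relay, of cell adhesion and of prespore and prestalk cells rose, while ribosomal protein and many starvation genes fell. From 0 to 8 h, acaA (adenylyl cyclase A, which makes the cAMP that is relayed; DDB_G0281545, chromosome 3, 4958602 to 4963128, plus strand) rose from 1.13 ± 0.418 to 382 ± 139 FPKM (log2 difference 7.45 ± 0.21 SE, adjusted p = 1.9e-20), and csaA, the adhesion protein of aggregating cells, by 8.69 (adjusted p = 1.3e-17). The most raised named genes were the calcium-binding protein genes cbpC (11.74), cbpF (11.33) and cbpA (10.80), the cysteine proteinase gene cprB (11.43), mrrA (11.13) and the prespore surface gene pspA (10.98). The most lowered were gp130 (-8.61), the urate oxidase gene uox (-7.84), sigI (-7.48), fhbB (-7.07), cxgS (-7.06) and alrA (-6.82). Of 28 tested cAMP relay genes, 23 rose and 2 fell (the same counts adjusted over the list alone). Of 12 prespore genes 10 rose and 1 fell, and of 18 prestalk genes 15 rose and 1 fell, with the same counts adjusted over the list alone. Of 16 aggregation and adhesion genes 12 rose and 1 fell, and of 22 starvation genes 16 fell and 1 rose, again the same adjusted over the list alone. All 78 ribosomal protein genes fell, over all genes and adjusted over the list alone (median -4.38). Of 42 proteasome subunit genes, 38 rose by 5 h (39 adjusted over the list alone, median 1.92). Of 31 replication and cell cycle genes, 27 fell by 1 h (27 adjusted over the list alone), and 28 rose by 8 h (29 adjusted over the list alone). In all, 4930 genes were called at 1 h (2590 up and 2340 down), 5458 at 2 h (2725 and 2733), 7671 at 5 h (3843 and 3828) and 7925 at 8 h (4106 and 3819). With only the groups compared in the fit, the 2 h count was 3489. With median-ratio scaling the larger direction turned to down at 5 h (3403 up and 4169 down) and 8 h (3754 and 3994).

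The same comparison within the mutant asked how far its cells moved in the same hours. Relay genes rose in the mutant as well, whereas prespore, prestalk and ribosomal protein genes mostly did not pass the test. At 8 h 22 of 28 relay genes had risen from 0 h (22 adjusted over the list alone): acaA by 4.22 (adjusted p = 4.6e-14) and csaA by 7.29 (adjusted p = 1.4e-14). Of the prespore genes 1 of 12 had risen (1 adjusted over the list alone), of 18 prestalk genes 1 had risen and 2 had fallen (1 and 1 adjusted over the list alone), and 1 of 78 ribosomal protein genes had fallen (0 adjusted over the list alone, 1 at an unadjusted p under 0.05 and 1 by limma voom, median -0.33). Of 31 replication genes, 18 had fallen and 2 had risen, with the same counts adjusted over the list alone. The mutant had 3928 called genes at 1 h (2009 up and 1919 down), 3458 at 2 h (1644 and 1814), 4196 at 5 h (1933 and 2263) and 4629 at 8 h (2106 and 2523). Of the 3158 genes with at least a 2-fold rise in the wild type at 8 h, 713 (22.6%) also rose at least 2-fold in the mutant. That need not be as large a rise as in the wild type. By independent lists 356 would be shared. Of the 3041 that fell at least 2-fold, 1227 (40.3%) also fell at least 2-fold in the mutant, with 458 for independent lists. At 1 h those shares were 45.9% of 1678 raised and 54.6% of 1577 lowered genes. The 2 strains share no libraries in these comparisons. The median change in the mutant of the 3158 genes was 0.30, against 2.15 in the wild type, where the genes were picked for their rise. That choice raises the wild type median but not the mutant's. Seen from the mutant, 1279 genes rose at least 2-fold by 8 h, 713 of them shared, and 1712 fell, 1227 of them shared.

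On the wild type axis over 6199 genes, wild type libraries lay at 0.142 ± 0.006 at 1 h, 0.234 ± 0.033 at 2 h and 0.730 ± 0.006 at 5 h. Mutant libraries lay at 0.034 ± 0.009 at 0 h, 0.155 ± 0.036 at 1 h, 0.157 ± 0.002 at 2 h, 0.200 ± 0.006 at 5 h and 0.252 ± 0.012 at 8 h. The mutant 1 h mean was raised by replicate 1 (0.197), 1 of the 4 libraries with few genes at exactly 1 read. Replicates 2 and 3 both lay at 0.134. The mutant was thus 0.530 behind at 5 h (a difference of -0.530) and differed by -0.748 at 8 h. The wild type 0 h and 8 h libraries define the axis, so only at 1, 2 and 5 h are both strains placed on equal terms. The exact permutation test gave p = 0.1 at 0, 2, 5 and 8 h, the smallest it can give, and p = 1 at 1 h (Benjamini-Hochberg adjusted 0.125 and 1 over the 5 times). Across genes, which are not independent replicates, mutant 8 h means correlated at 0.911 with wild type 2 h and at 0.631 with wild type 8 h.

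**Figure D1:**
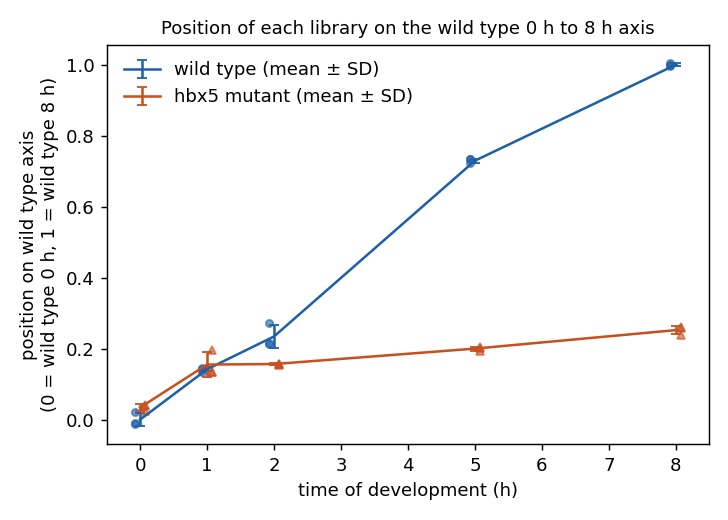
Position of each of the 30 libraries on the wild type axis (vertical, no unit; 0 is the wild type 0 h mean and 1 the wild type 8 h mean) against time in h (horizontal); points are libraries, lines join group means and bars are SD, n = 3. The mutant 8 h libraries lay from 0.239 to 0.260, above wild type 2 h replicates 1 and 2 (0.214 and 0.216) and below replicate 3 (0.273), which is 1 of the 4 libraries with few genes at exactly 1 read.

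Cells at 0 h were compared to see how the strains differed before development. Discoidin lectin genes, smlA and cadA were lower in the mutant, as were 10 of 28 cAMP relay genes (6 without any 1 of wild type 0 h replicate 1 and mutant 0 h replicates 1 and 3). The gene smlA, which controls the size of aggregates (DDB_G0287587, chromosome 5, 461888 to 462739, plus strand), was at 6.76 ± 1.92 FPKM in the mutant against 2469 ± 164 FPKM in the wild type (log2 difference -8.34 ± 0.26 SE, adjusted p = 2.1e-17). The calcium-dependent adhesion gene cadA was at 579 ± 139 against 13360.0 ± 1494 FPKM (log2 difference -4.55 ± 0.29 SE, adjusted p = 1.4e-11), mutant first. The inhibitor gene of the secreted cAMP phosphodiesterase, pdiA, was at 1.90 ± 0.832 against 555 ± 49.7 FPKM (log2 difference -7.62 ± 0.31 SE, adjusted p = 1.8e-15). Also among the most lowered were DD7-1 (-8.31) and the copy-uncertain discoidin lectin genes dscD-1 (-8.07), dscC-1 (-7.99), dscC-2 (-7.92) and dscD-2 (-7.72). The most raised were ponC3 (3.12), ponC5 (2.94), ponC1 (2.79), the homeobox gene warA (2.35), sibC (2.26) and the countin family gene ctnB (2.14), with adjusted p from 4.4e-10 for warA to 0.017 for sibC. The sibC call was lost without any 1 of wild type 0 h replicates 1 and 2 and mutant 0 h replicates 2 and 3 (adjusted p = 0.114, 0.0610, 0.0742 and 0.0563). Of 28 relay genes 10 were lower and 18 were not called (12 lower adjusted over the list alone, median -0.44; adjusted p = 1.5e-06 by camera, adjusted p = 0.026 with an estimated correlation). They included regA (the intracellular cAMP phosphodiesterase, -1.86), the MAP kinase gene erkA (-1.47) and pdsA (the secreted cAMP phosphodiesterase, -1.47), while acaA was at 0.802 ± 0.190 against 1.13 ± 0.418 FPKM (adjusted p = 0.57). Of 22 starvation and cell counting genes 10 were lower and 2 higher (the same counts adjusted over the list alone; adjusted p = 7.1e-06 by camera, adjusted p = 0.19 with an estimated correlation). That list's median was 0.03 and its mean -2.11, since 7 of the 10 lower genes were discoidin genes, counted with both copies where the reference holds 2. Of its 22 members 8 have a second copy or lie in the duplicated stretch. At every time the counts and camera take such near-identical entries as separate members. Of 16 aggregation and adhesion genes 2 were higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.20 by camera, adjusted p = 0.70 with an estimated correlation). In all, 1727 genes were called, 757 higher and 970 lower in the mutant, 301 and 648 of them by at least 2-fold. Without the 4 libraries with few genes at exactly 1 read, none of which is a 0 h library, 2977 genes were called (1470 higher and 1507 lower), through the spread that all groups share.

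At 1 and 2 h the comparison asked how the transcripts of relay genes differ in the first hours. Relay genes were lower in the mutant. Most replication genes were higher (adjusted p = 0.15 at 1 h and adjusted p = 0.27 at 2 h with an estimated correlation). At 1 h acaA was at 2.49 ± 0.411 FPKM in the mutant against 80.4 ± 6.92 FPKM in the wild type (log2 difference -4.55 ± 0.21 SE, adjusted p = 6.8e-15). The phosphodiesterase gene pdsA was at 48.1 ± 12.9 against 2179 ± 280.2 FPKM (log2 difference -5.50 ± 0.28 SE, adjusted p = 7.9e-14), mutant first. The cAMP receptor gene carA-1, which is copy-uncertain, differed by -3.33 and csaA by -1.93 on the log2 scale. Of 28 relay genes 18 were lower at 1 h and 19 at 2 h, with no other called (20 and 22 lower adjusted over the list alone, medians -1.03 and -1.20). At 1 h this gave adjusted p = 2.2e-09 by camera, adjusted p = 0.0064 with an estimated correlation, and at 2 h adjusted p = 2.4e-10 by camera, adjusted p = 0.0064 with an estimated correlation. At 2 h acaA differed by -5.28, regA by -3.73, and gpaB, the G protein subunit coupled to the receptor, was at 157 ± 11.1 against 680.5 ± 89.96 FPKM (log2 difference -2.11 ± 0.19 SE, adjusted p = 2.1e-09). The most lowered at 1 h were smlA (-9.61) and 5 discoidin genes (-8.97 to -8.13), and at 2 h prtB (-9.26), pdiA (-9.10), smlA (-9.03) and 3 discoidin genes (-7.93 to -7.73). Among the most raised at 1 h were stkA (3.28), manE (2.96), pssA (2.76), cprC (2.71) and the replication gene cdc45 (2.63), and the most raised at 2 h were ctnB (4.41), the sterol reductase gene erg24 (3.66), vacB (3.55), hmgB (3.45), ponM (3.42) and redA (3.23).

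Of 31 replication and cell cycle genes 23 were higher in the mutant at 1 h (24 higher and 1 lower adjusted over the list alone, median 1.52; adjusted p = 2.5e-11 by camera, adjusted p = 0.15 with an estimated correlation). At 2 h 24 were higher and 2 lower (25 and 2 adjusted over the list alone, median 1.04; adjusted p = 2.9e-07 by camera, adjusted p = 0.27 with an estimated correlation). Among them were the mitotic kinase gene aurK at 16.8 ± 3.002 against 1.97 ± 0.155 FPKM at 1 h (log2 difference 2.57 ± 0.20 SE, adjusted p = 2.4e-10), the DNA polymerase gene polA1 (2.36 at 1 h) and the ribonucleotide reductase gene rnrA (2.33 at 2 h). Starvation genes were lower for 13 of 22 members and higher for 1 at 1 h (the same adjusted over the list alone; adjusted p = 2.3e-08 by camera, adjusted p = 0.094 with an estimated correlation). At 2 h 9 were lower and 1 higher (the same adjusted over the list alone; adjusted p = 3.5e-04 by camera, adjusted p = 0.28 with an estimated correlation). Proteasome genes were lower for 25 of 42 at 1 h (32 adjusted over the list alone, median -0.74; adjusted p = 7.1e-06 by camera, adjusted p = 0.52 with an estimated correlation), and for 15, 13 and 7 without wild type 1 h replicates 1 or 2 or mutant 1 h replicate 1. At 2 h 20 were lower and 1 higher (21 and 1 adjusted over the list alone; adjusted p = 5.1e-05 by camera, adjusted p = 0.62 with an estimated correlation), and 31 lower without wild type 2 h replicate 3. Lysosomal enzyme genes of feeding cells were lower for 5 of 24 and higher for 1 at 0 h. At 1 h 7 were lower and 1 higher (4 lower without mutant 1 h replicate 1). Camera called this list at neither time with all libraries. At 1 h it did so in 7 alternatives, a pseudocount of 0.1 and no filter among them (adjusted p from 0.018 to 0.044). At 2 h 9 of 24 were higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.019 by camera, adjusted p = 0.76 with an estimated correlation), a call lost without wild type 2 h replicate 3 (5 higher and 4 lower, adjusted p = 0.403). In all, 3289 genes were called at 1 h (1633 higher and 1656 lower) and 3953 at 2 h (2004 and 1949). With median-ratio scaling the 1 h split was 1711 and 1628, so its direction is not settled. Without the 4 libraries with few genes at exactly 1 read the 2 h split was 2115 and 2217, so that direction is not settled either. With only the groups compared in the fit, the 2 h count was 2381.

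**Figure D2:**
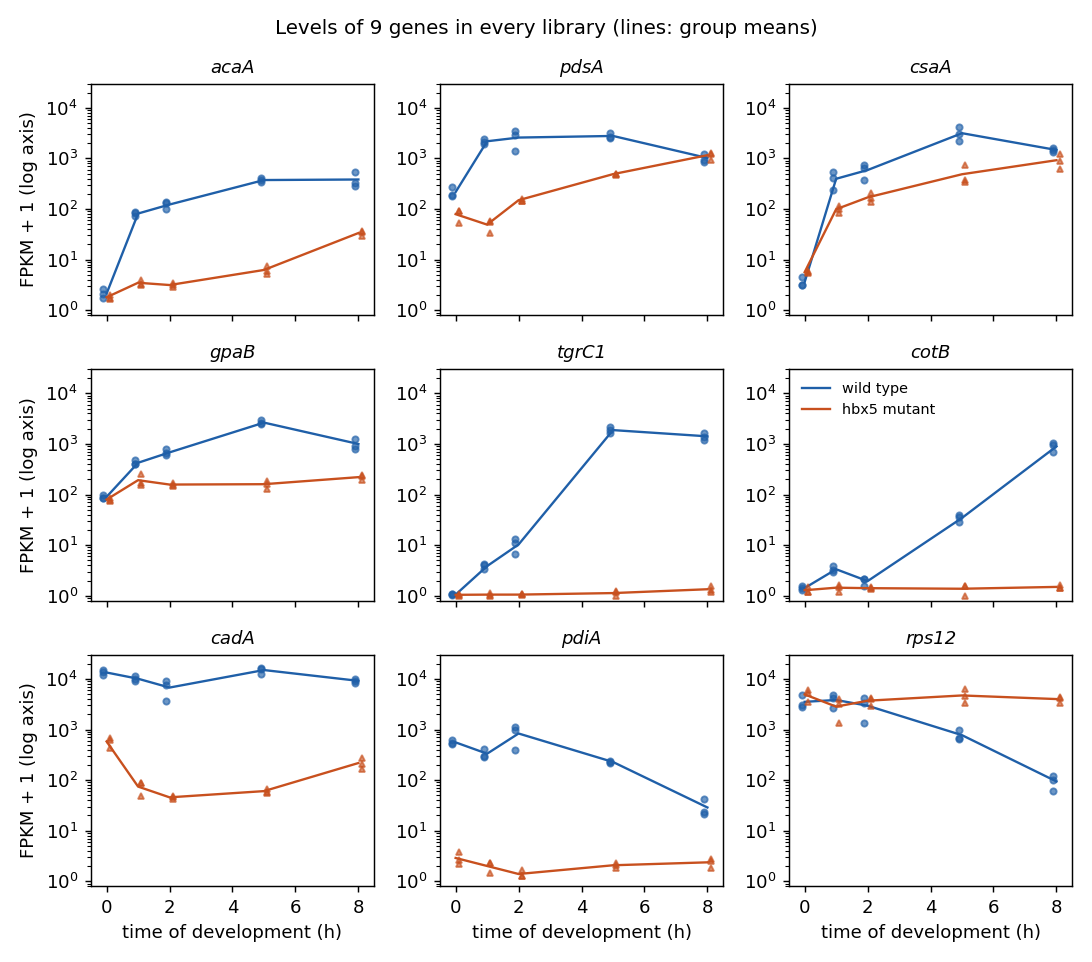
Levels of 9 genes (vertical, FPKM + 1 on a log axis) against time in h (horizontal) in wild type (circles) and mutant (triangles) libraries, n = 3 per group; lines join group means. In the wild type acaA reached 80.4 FPKM by 1 h and tgrC1 1877 FPKM by 5 h, while acaA was at 32.5 FPKM and tgrC1 at 0.346 FPKM in the mutant at 8 h.

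At 5 h, when wild type cells aggregate, the recognition genes tgrC1 and tgrB1 and 22 of 28 relay genes were lower in the mutant, and 40 of 42 proteasome genes were lower (adjusted p = 0.19 with an estimated correlation). The recognition gene tgrC1 (DDB_G0280531, chromosome 3, 3630672 to 3633406, minus strand) was at 0.131 ± 0.115 FPKM in the mutant against 1877 ± 246 FPKM in the wild type (log2 difference -10.69 ± 0.19 SE, adjusted p = 9.1e-24). Its partner tgrB1 was at 3.08 ± 0.343 against 2177 ± 248 FPKM (log2 difference -9.06 ± 0.26 SE, adjusted p = 8.6e-20), mutant first. The most lowered were cbpC (-12.17), cbpE (-11.64), mrrA (-11.41), cbpA (-11.12), tgrC1 and prtB (-10.41). Of 28 relay genes 22 were lower and 1 higher (the same adjusted over the list alone, median -1.60; adjusted p = 3.4e-06 by camera, adjusted p = 0.026 with an estimated correlation). Among these acaA was at 5.25 ± 1.24 against 372 ± 33.9 FPKM (log2 difference -5.92 ± 0.21 SE, adjusted p = 4.5e-18). The receptor gene carC differed by -7.41, gpaB by -4.05 and pkaR, the regulatory subunit of cAMP-dependent kinase, by -3.16. The kinase gene pkbA was the member that was higher (1.77). Of 42 proteasome genes 40 were lower (40 adjusted over the list alone, median -2.84; adjusted p = 1.2e-12 by camera, adjusted p = 0.19 with an estimated correlation), such as psmD4 at 77.3 ± 5.50 against 775 ± 86.8 FPKM and psmA7 (-3.17). Ribosomal protein genes were higher for 45 of 78 (45 adjusted over the list alone, median 1.31; adjusted p = 7.3e-05 by camera, adjusted p = 0.76 with an estimated correlation). At 0, 1 and 2 h limma called 0 of the 78, against 0, 1 and 0 at an unadjusted p under 0.05, and voom called 0 at each.

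Lysosomal enzyme genes were higher for 16 of 24 and lower for 4 at 5 h (the same adjusted over the list alone, median 3.19; adjusted p = 0.0023 by camera, adjusted p = 0.76 with an estimated correlation). The cysteine proteinase gene cprD was at 480.2 ± 68.2 against 8.76 ± 1.33 FPKM (log2 difference 5.62 ± 0.28 SE, adjusted p = 6.9e-15), and nagD was among the lower members (-9.03). Also among the most raised were erg24 (4.93), hydA (4.82), maoA (4.74), omt9 (4.72) and gerD (4.68). Aggregation and adhesion genes were lower for 8 of 16 and higher for 2 (the same adjusted over the list alone; adjusted p = 0.0020 by camera, adjusted p = 0.15 with an estimated correlation). Of 18 prestalk genes 10 were lower and 2 higher (the same adjusted over the list alone; adjusted p = 0.010 by camera, adjusted p = 0.28 with an estimated correlation). Of 12 prespore genes 4 were lower and 2 higher (the same adjusted over the list alone; adjusted p = 0.65 by camera, adjusted p = 0.95 with an estimated correlation). Replication genes were higher for 10 of 31 and lower for 3 (the same adjusted over the list alone; adjusted p = 0.34 by camera, adjusted p = 0.95 with an estimated correlation). Of 22 starvation genes 9 were higher and 9 lower (the same adjusted over the list alone; adjusted p = 0.85 by camera, adjusted p = 0.96 with an estimated correlation). In all, 7427 genes were called, 3567 higher (2805 by at least 2-fold) and 3860 lower (2807). Median-ratio scaling moved the median difference of all genes by 0.114 at 5 h and 0.113 at 8 h; with it 3948 genes were higher (3062 by at least 2-fold) and 3349 lower (2389) at 5 h, so the larger direction turns. With it the ribosomal protein median at 5 h was 1.52 and the proteasome median -2.63.

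At 8 h 10 of 12 prespore and 14 of 18 prestalk genes were lower in the mutant, and 78 of 78 ribosomal protein genes were higher (adjusted p = 0.27, 0.066 and 0.27 with an estimated correlation). The spore coat gene cotB (DDB_G0276761, chromosome 2, 7194376 to 7196288, plus strand) was at 0.497 ± 0.124 FPKM in the mutant against 895 ± 182 FPKM in the wild type (log2 difference -9.21 ± 0.20 SE, adjusted p = 2.2e-22). The most lowered were cbpC (-12.06), pspA (-10.86), mrrA (-10.40), the spore coat gene cotC (-10.23), glpD (-10.23) and cbpA (-10.09). Of 12 prespore genes 10 were lower and 1, spiA, was higher (the same adjusted over the list alone, median -6.52; adjusted p = 7.5e-05 by camera, adjusted p = 0.27 with an estimated correlation). Of 18 prestalk genes 14 were lower and 1 higher (the same adjusted over the list alone; adjusted p = 1.1e-05 by camera, adjusted p = 0.066 with an estimated correlation), among them rasD (-8.19), cudA (-7.41) and tagB (-5.57). Of 16 aggregation genes 11 were lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 7.7e-06 by camera, adjusted p = 0.026 with an estimated correlation). All 78 ribosomal protein genes were higher (78 adjusted over the list alone, median 4.37; adjusted p = 3.2e-20 by camera, adjusted p = 0.27 with an estimated correlation), for instance rps12 at 3993 ± 594 against 93.0 ± 30.1 FPKM (log2 difference 5.45 ± 0.41 SE, adjusted p = 2.1e-11). Replication genes were lower for 30 of 31 (30 adjusted over the list alone, median -2.51; adjusted p = 9.1e-08 by camera, adjusted p = 0.27 with an estimated correlation), with aurK at 8.85 ± 1.75 against 123 ± 14.1 FPKM and cdc20 at -3.38.

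At 8 h relay genes were mostly lower in the mutant. Of 28 relay genes 17 were lower and 2 higher (the same adjusted over the list alone, median -1.04; adjusted p = 0.0095 by camera, adjusted p = 0.27 with an estimated correlation). The cyclase gene acaA was at 32.5 ± 3.73 against 382 ± 139 FPKM (log2 difference -3.46 ± 0.21 SE, adjusted p = 1.6e-13). Not called were pdsA at 1155 ± 180.1 against 1017 ± 202 FPKM (adjusted p = 0.58), csaA at 919 ± 311 against 1465 ± 134 FPKM (adjusted p = 0.057) and regA, with a difference of 0.05 (adjusted p = 0.83). The 2 higher were pkbA (3.67) and rasG (1.43, adjusted p = 0.019), the latter not called without mutant 8 h replicate 1 (adjusted p = 0.0582). Lysosomal enzyme genes were higher for 14 of 24 and lower for 3 (the same adjusted over the list alone; adjusted p = 0.024 by camera, adjusted p = 0.76 with an estimated correlation), a call lost without wild type 8 h replicate 1 (adjusted p = 0.0523). Proteasome genes were lower for 31 of 42 and higher for 3 (33 and 3 adjusted over the list alone; adjusted p = 0.0065 by camera, adjusted p = 0.76 with an estimated correlation). Starvation genes were higher for 8 of 22 and lower for 5 (the same adjusted over the list alone; adjusted p = 0.25 by camera, adjusted p = 0.83 with an estimated correlation), with aprA, a secreted repressor of proliferation, at 550.4 ± 64.0 against 15.3 ± 0.619 FPKM and the countin gene ctnA at 4.13. Also among the most raised were the copy-uncertain rpl15-2 (5.86), alyL (5.17), the glucosidase gene gluA (5.14) and rps23 (5.08). In all, 7363 genes were called, 3426 higher (2581 by at least 2-fold) and 3937 lower (2931). With median-ratio scaling 3692 were higher (2815) and 3575 lower (2664), so the larger direction turns here too.

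Members of the 4 other lists moved both ways, and camera called none of them at any of the 5 times with all libraries. Heat shock genes at 0 h were called without wild type 0 h replicate 2, wild type 2 h replicate 3, or mutant 0 h replicates 1 or 2 (adjusted p = 0.0072, 0.045, 0.029 and 0.029). Counts at 8 h were 6 higher and 9 lower of 21 GATA factor genes, 1 and 4 of 12 homeobox genes, 3 and 3 of 13 autophagy genes (each the same adjusted over the list alone), and 3 and 11 of 29 heat shock and stress genes (2 and 8 adjusted over the list alone). Without wild type 8 h replicate 1, 3 GATA factor genes were higher, and without wild type 8 h replicate 2 or mutant 8 h replicate 3, 7 and 6 heat shock genes were lower. The homeobox gene warA went from 2.35 at 0 h to -4.65 at 8 h. With the preset correlation camera called 25 of 65 pairs of list and time, and 5 with the estimated one: the relay list at 0, 1, 2 and 5 h and the aggregation list at 8 h.

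**Figure D3:**
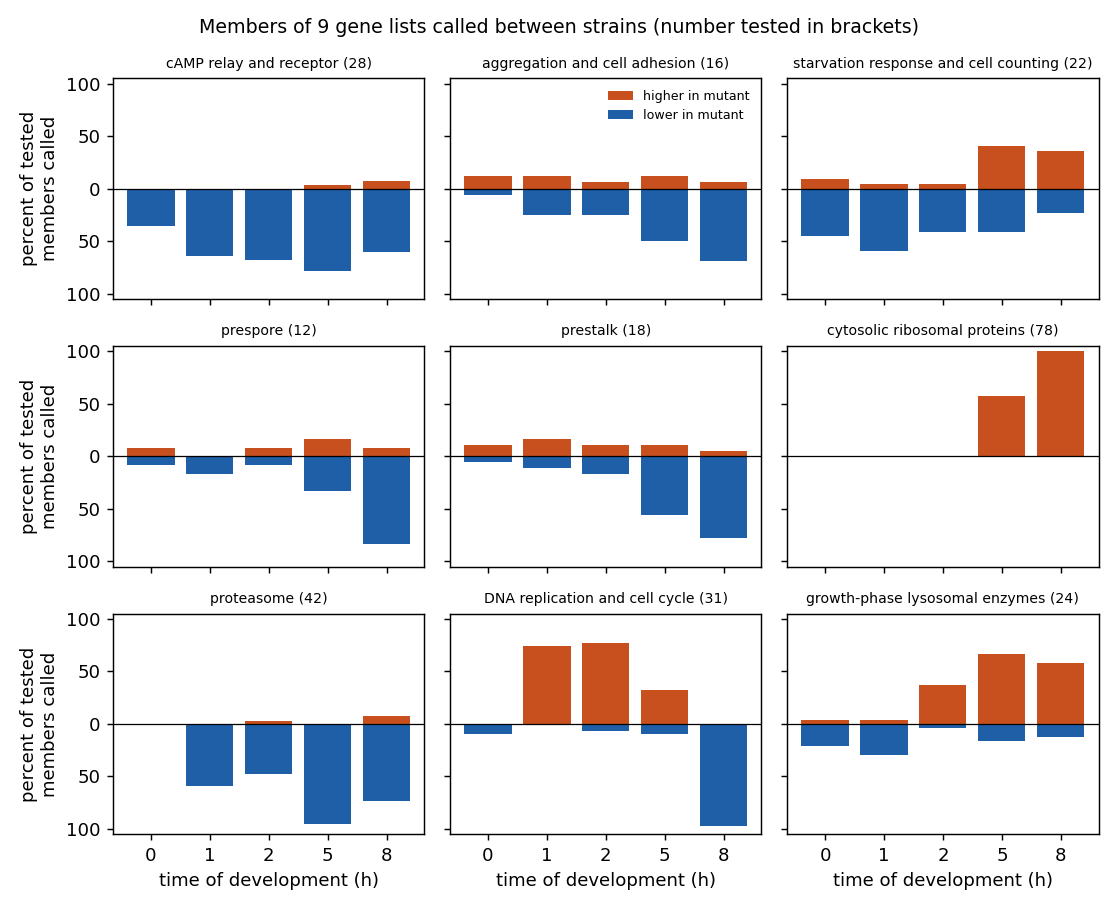
Percent of tested members of 9 gene lists (vertical; number tested in brackets) called higher (up) or lower (down) in the mutant by limma at each time in h (horizontal). Ribosomal protein genes were called at 5 h (45 of 78) and 8 h (78 of 78), and replication genes were higher for 23 of 31 at 1 h and lower for 30 of 31 at 8 h.

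The interaction tested whether the change since 0 h differed between strains. For acaA the mutant's change differed by -4.32 ± 0.29 (adjusted p = 1.7e-10) at 1 h and by -3.23 ± 0.29 (adjusted p = 9.1e-10) at 8 h, a smaller rise. For pdsA it differed by -4.03 ± 0.40 (adjusted p = 9.7e-08) at 1 h, and by 1.66 ± 0.40 (adjusted p = 0.0011) at 8 h, so the mutant's rise was then the larger. For regA it differed by 1.91 ± 0.27 (adjusted p = 1.5e-06) at 8 h. Ribosomal protein genes fell less in the mutant by 8 h for 76 of 78 (77 adjusted over the list alone), and replication genes differed downward for 29 of 31 and upward for 1 (the same adjusted over the list alone). In all, 1355 genes were called at 1 h (685 with a higher and 670 with a lower change in the mutant), 1964 at 2 h (1090 and 874), 6107 at 5 h (2999 and 3108) and 5924 at 8 h (2715 and 3209). With median-ratio scaling the larger direction turned at 5 h (3264 higher and 2646 lower) and 8 h (2941 and 2939). Without the 4 libraries with few genes at exactly 1 read the 1 h count was 2204, and with only the groups compared in the fit the 2 h count was 1298.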

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

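Chosen only after the results were seen were the tests of splits of 6 libraries, of wild type RNA in the mutant samples, of the share of lowered genes outside the stretch, of read levels in the duplicated stretch, of the sampling time of the 0 h libraries, of the later course of the 0 h genes at 1 and 2 h, of depth and, for each of 4 libraries, of lost transcripts; the others were written down before. The difference between strains in the change since 0 h was itself tested with limma, and it was called for 1355 genes at 1 h, 1964 at 2 h, 6107 at 5 h and 5924 at 8 h. Strain labels were exchanged within the time and within 0 h in 100 splits. As many genes came from 8 of them at 1 h (highest other 3510), 8 at 2 h (highest other 2865), 1 at 5 h, the real split (highest other 6095), and 5 at 8 h (highest other 6685). Of the other splits that reached the real count, 7 of 7 at 1 h, 7 of 7 at 2 h and 4 of 4 at 8 h kept the real labels at the later time, and so did the highest other at 5 h. Such splits keep the strain difference at that time, a structure of the samples, so these shares do not test the interaction and say nothing on chance.

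For the 13 comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes. The real counts and the highest of the other splits were 1727 and 19 between strains at 0 h, 3289 and 0 at 1 h, 3953 and 50 at 2 h, 7427 and 1 at 5 h, and 7363 and 1 at 8 h. For the wild type against 0 h they were 4930 and 1, 5458 and 242, 7671 and 1, and 7925 and 2 at 1, 2, 5 and 8 h, and for the mutant 3928 and 11, 3458 and 0, 4196 and 8, and 4629 and 0. For the gene lists, 2 of 100 exchanges of strain labels within each time, the real labels among them, gave as many called pairs (25 real, 26 the highest other). That is under the 5 of 100 written down before. An exchange could keep the real labels at some times, and exchanges cover only the spread between technical replicates. The share therefore does not exclude chance differences between cultures, and the total rests on the preset correlation.

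Libraries labelled hbx5 mutant hold hbx5 reads, and hbx5 is lower in them by the test at 5 h alone among the 5 times. Wild type RNA mixed into the mutant samples is argued against: over 526 genes strongly induced in the wild type at 8 h, the 10th percentile of the mutant level was 0.0546% of the wild type level, whereas hbx5 was at 115% or more. A loss of reads over the whole duplicated stretch stays open as a cause of the lower value at 5 h: 24.3% of the other genes there (93 of 382) were lowered as much, but the planned bound of 5% had no baseline, and outside the stretch the share was 20.5%. Among genes near the level of hbx5 at the other times the share was 31.0% of 142 inside and 13.6% of 2294 outside, and it was the larger inside in each of 7 ways of choosing the genes, with medians inside from -1.38 to -0.32. Sharing of reads between copies remains a candidate explanation for low levels in the stretch, with a median log2 level -2.21 relative to the rest of chromosome 2 (1.38 against 3.59), and an altered gene that is still transcribed was not tested.

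Genes lower by at least 2-fold in the mutant at 0 h (648) were weighed next. Reads shared between near-identical copies are argued against, since 3.55% of them (23 genes) lie in the stretch or have a second copy, and so is a sampling at another time, since 3 of 3 mutant libraries correlated best with wild type 0 h (0.948 or more, against 0.831 or less with the next group). A state of the cells at harvest that was gone by 2 h is argued against, since 444 of the genes were lower and 18 higher at 1 h (median -1.62), and 431 and 20 at 2 h (median -1.54). Whether the difference lasts beyond that stays open for the 648 genes as a set. Their median at 5 h was -0.347, inside the limits of -0.5 to 0.5 written down for no lasting difference. But 283 were then lower and 158 higher, so the median decides nothing. For 107 of the genes the difference did last, since they were at least 2-fold lower at all 5 times. A lasting effect of the mutation stays open, as does any difference in growth between the cultures, which the labels do not describe.

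In 4 libraries fewer than 200 genes had exactly 1 read: wild type 2 h replicate 3 (133 genes), mutant 1 h replicate 1 (173), mutant 5 h replicate 3 (95) and mutant 8 h replicate 2 (143), against 290 to 503 in the other 26. Lower depth is argued against, since 0 of the 4 had fewer reads than the lowest of the others (16466444 to 20245676 reads in the 4, against 12977573 as the lowest). Loss of rare transcripts before amplification may account for the first 3, in which 89, 7 and 203 genes with at least 20 reads in both other libraries of the group had no read, against 1 as the highest of the other 26. In mutant 8 h replicate 2 the number was 0, so that library stays open. A single forecast for all 4 had been written down before and failed for this library, and the test for each library replaced it. No biological explanation was tested here.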

How the results depend on the processing

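Limma voom, the omission of 4 libraries with few genes at exactly 1 read and the omission of the duplicated stretch were chosen only after the results were seen. A pseudocount of 0.1 gave position differences of -0.548 at 5 h and -0.765 at 8 h, and axis genes with a 4-fold change gave -0.521 at 5 h. With only the groups compared in the fit, 2381 genes were called between strains at 2 h, 3489 in the wild type at 2 h and 1298 for the interaction at 2 h. With an estimated correlation camera called 5 pairs. Without the 4 libraries, 2977 genes were called between strains at 0 h and 2204 for the interaction at 1 h, and the rasG difference at 2 h was -0.68 (adjusted p = 0.0033), against 0.41 (adjusted p = 0.60, not called) with all libraries. Leaving out 1 library at a time gave position differences from -0.533 to -0.521 at 5 h and from -0.753 to -0.736 at 8 h. Voom gave 0.755 to 1.009 times the counts of limma-trend, median-ratio scaling 0.968 to 1.029 times, and the replicate number as a block 1 to 1.092 times. Of 4511 values of named genes under other alternatives, 4416 kept their call, 47 lost it, 47 gained one and 1 reversed; of 3078 with a library left out, 2943 kept it, 107 lost it and 28 gained one. Of 390 values of a list at a time, 366 kept their call, 21 lost it and 3 gained one; of 1950 with a library left out, 1930 kept it, 2 lost it and 18 gained one. The gains include ribosomal proteins at 0 h (adjusted p from 0.0022 to 0.037 without wild type replicate 3 or mutant replicates 1 or 3), 1 h (0.017 and 0.020 without wild type replicate 1 or mutant replicate 2) and 2 h (0.0087 and 0.035 without wild type replicate 2 or mutant replicate 1).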

Other observations

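The tests of gene families and of genes changed at all times were chosen only after the results were seen, while the test of a uniform delay was written down before, without its runs with libraries left out. Genes of the tgr family, which holds the recognition genes tgrB1 and tgrC1, were lower in the mutant at 8 h for 27 of 30 members and higher for 1 (median -5.73), and rose in the wild type by 8 h for 28 of 30. Of 15 tested members of the cbp family of calcium-binding proteins 12 were lower and 1 higher at 2 h (median -2.91). Of 19 ddx helicase genes 14 were higher at 2 h (median 1.41), and 9 of 9 utp genes of ribosome assembly (median 1.67). Over 83 families and 5 times camera called 64 of 415 pairs with the preset correlation and 0 with the estimated one, where adjusted p was 0.16 for tgr and cbp, 0.34 for ddx and 0.635 for utp.

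At all 5 times 107 genes were at least 2-fold lower in the mutant, with 0.419 from independent lists, and 62 at least 2-fold higher, with 0.137. The lists share no libraries, but they share the spread of 1 fit and compare the same 2 strains. Any lasting difference between the strains or their cultures raises the overlap, so the numbers from independent lists do not test its cause. Among the higher were ctnB (smallest change 2.14) and hmgB (1.64).

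On the axis the mutant 8 h libraries (0.239 to 0.260) lay above wild type 2 h replicates 1 and 2 (0.214 and 0.216). They lay below replicate 3 (0.273), which is 1 of the 4 libraries with few genes at exactly 1 read. A uniform delay along the wild type course could give such a position. The test did not settle it. Of 139 genes that were not called at 0 h, rose at least 2-fold in the wild type by 1 and 2 h, and whose mean log2 level there was no lower at 2 h than at 1 h and higher at 5 h, 22 (15.8%) were below the wild type 1 h level and 11 (7.91%) above the wild type 2 h level, more than the 5% on each side that had been written down against a delay. Above were 5.11% without wild type 2 h replicate 3 and 4.10% without the 4 libraries with few genes at exactly 1 read. In these runs 22.6% and 25.4% were below. By its bound on both sides the test therefore left a uniform delay open. With any 1 library left out, 15% to 22.6% were below. On the axis, mutant 8 h libraries lay past every wild type 1 h library (0.135 to 0.146). A delay to a time after 1 h would leave no steadily rising gene below its wild type 1 h level. The genes below thus argue against a uniform delay for this set, though picking genes by their wild type rise can enlarge that share. Below were tgrB1, tgrC1, acaA and gpaB, and above were rrpA, aph1 and hbx2. The remaining 106 were called on neither side, which does not show that they match. Over all tested genes, mutant 8 h libraries lay at -26.1 to -20.4 on the first principal component. Wild type libraries lay at -39.2 to -36.4 at 1 h and -17.2 to -3.33 at 2 h. On the next component the mutant 8 h libraries lay at 1.56 to 3.88, against 69.1 to 71.3 and 74.8 to 75.7. These values too argue against a uniform delay as the only difference between the strains.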
